A study of Homo sapiens with 23 samples.

How the data were processed

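The series holds 23 libraries of total RNA from a pair of established human cell lines, hTERT-RPE1 and SH-SY5Y, each labelled wild type or SDCCAG8 knockout and grown in 10% serum or in 0.1% serum for 48 h. RNA was extracted with RNeasy and libraries were made with TruSeq, per the labels' protocols. The deposited values are read counts per gene, made with STAR and HTSeq per the submitters' processing notes, with no version stated. The genome build, gene annotation and strand setting were not given in the sources used here. Each deposited count file listed 55765 gene symbols and 5 special HTSeq entries for reads that were not assigned to a gene. These entries were left out of all totals and tests. Reads without a gene made up 2.95 to 6.2% of all reads per library, ambiguous reads 1.98 to 2.5% and reads without a unique position 17.4 to 22.2%, so 22.5 to 30.3% went unassigned.

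Libraries were grouped by line, genotype and condition from the labels alone, giving 8 groups. Deviations of same-number libraries from their group means were correlated. All correlations were over 0.1 for SH-SY5Y libraries labelled knockout against WT at baseline (0.432 to 0.536) and starved (0.207 to 0.555). The same held for starvation of those labelled knockout (0.353 to 0.888). By this rule the numbers pair the libraries there, though no label says so. The rule is loose, since baseline library 1 of those labelled knockout correlated at 0.619 with starved library 2 and at 0.764 with its own number. The main fits did not use the pairing. Knockout against WT in starved RPE1 had only 2 such pairs, both over 0.1 (0.456 and 0.849), which were too few to decide, and in each other comparison at least 1 pair was not over 0.1. Replicate 1 of the starved RPE1 knockout group was not analysed here, which left 2 libraries in that group and 3 in every other. The labels do not say whether replicates were separate cultures or how many edited clones were used. The p-values therefore measure only the spread between these samples, part of which may be technical, and a genotype difference cannot be separated from a difference between clones. A chi-square comparison of the counts of replicates gave 7.67 to 192 per degree of freedom over 22 pairs, so no pair was a copy of another.

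Tests were run in R 4.3.3 with edgeR 4.0.16. Each line was fitted on its own with 1 factor of 4 groups, TMM scaling (factors 0.918 to 1.076 in RPE1 and 0.977 to 1.034 in SH-SY5Y), filterByExpr (minimum count 10, minimum total 15) and robust quasi-likelihood F tests. This kept 17663 genes in RPE1 and 19390 in SH-SY5Y. The biological coefficient of variation was 0.111 and 0.12. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05. There were 10 comparisons, namely knockout against wild type in each line and condition, starved against baseline in each line and genotype, and the interaction of genotype and starvation in each line. Errors are standard errors of the fitted log2 fold change, and levels are group means ± SD of normalised count values in CPM. Shared calls were set beside the number expected if calls were independent, and for all 4 genotype comparisons if the lines were independent given the calls each shared across conditions.

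Where every library of a group had 0 reads, a fold is given as at least the level of the other group over a floor of 3 counts divided by the summed effective library size of the empty group. Where such a group had 1 to 3 reads, a ratio is given with an exact Poisson 95% interval. Floors and intervals cover counting error only. Genes whose symbols share reads with another gene are given as uncertain.

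The axon guidance list, and possibly others, was not chosen blind to earlier work on these cells. The 24 gene lists and the rule for naming genes were fixed before the data were examined, as were the comparisons, their tests and the other settings tried, while some tests of explanations were added after the results were seen, as stated with them. The lists covered centrosome and satellite, cilium and intraflagellar transport, hedgehog, WNT, Notch, p53, mitosis, replication, growth-factor response, YAP and Hippo, FOXO and quiescence, cholesterol, matrix, axon guidance, synapse, noradrenergic neuron, mesenchymal marker, retinal epithelium identity, interferon, stress response, cytosolic ribosome, mitochondrially encoded, glial and SDCCAG8 neighbour genes. Of 683 list members 679 matched a symbol, and CEP83, IFT22, TIGAR and SUSD6 did not. Named genes were the 8 largest called changes per direction in genotype comparisons, 6 in starvation and 4 in interactions, among genes at 5 CPM or more in a group, with 3 genes per list. For these largest changes, clone-type, uncharacterised, antisense and pseudogene symbols were left out. Outside interactions, the CPM of the libraries of both groups also had to be free of overlap. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 24 lists, and again with the correlation estimated from the data. Counts adjusted over the list alone apply the Benjamini-Hochberg step to list members only.

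A GENCODE 29 annotation was used only for chromosome, neighbour order and gene type, and gave a chromosome to 85.4% of tested genes in RPE1 and 82.6% in SH-SY5Y. Chromosome deviations are the median log2 fold change of a chromosome's genes minus that of all genes, for chromosomes with at least 100 genes, and windows held 50 to 57 neighbouring genes. Where list medians are given with chromosome medians subtracted, the median of all genes was added back to each gene. Genes without a known chromosome kept their value, and no gene was left out for its chromosome.

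The fits were tested on simulated data drawn from the real means and library sizes, with 200 genes changed by known folds. Over 10 comparisons and 17098 to 19006 genes, 9.09 to 50.7% of 1.5-fold changes were recovered, 53.1 to 78.8% of 2-fold changes and 81.5 to 93.8% of 4-fold changes. The highest share of false calls was 9.01%, and 10 of 10 raised lists and 0 unchanged lists were called. In the real data 34.2 to 52.6% of genes were called when groups were compared directly, so these shares need not carry over. Genes were simulated independently and the unchanged lists were random. The simulation therefore cannot show how camera treats lists whose genes move together.

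The alternatives tried were RLE scaling, DESeq2 1.42.0, no filter, glmTreat against a 1.5-fold change and the replicate number as a block. A stricter filter asked for 5 CPM in 3 libraries in SH-SY5Y and in 2 in RPE1, the size of its smallest group. Further alternatives were only the compared groups in the fit, each library left out in turn, the fry test and the estimated correlation. Depth was 38.6 to 115 M assigned reads per library, with 20202 to 25562 genes detected.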

Results

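Messenger and other total RNA was counted per gene in 23 libraries from a pair of established human cell lines, hTERT-RPE1 (telomerase-immortalised retinal pigment epithelium, called RPE1 below) and SH-SY5Y (a neuroblastoma line of immature sympathetic neuron type). Each line was labelled wild type (WT) or knockout (KO) for SDCCAG8, which encodes a centrosome and centriolar satellite protein involved in building the primary cilium and mutated in a human ciliopathy. Cells were taken in 10% serum (baseline) or after 48 h in 0.1% serum (starved), a treatment that commonly brings cells out of the cell cycle and lets cilia form. Each of the 8 groups held 3 libraries, except RPE1 KO starved with 2 (replicates 2 and 3). Reads assigned to genes numbered 38.6 to 94.2 M per library in RPE1 and 48.3 to 115 M in SH-SY5Y. A test was possible for 17663 genes in RPE1 and 19390 in SH-SY5Y. The sympathetic neuron genes PHOX2A, DBH, ISL1 and ELAVL4 had 0 reads in every RPE1 library. TH, of the noradrenergic list, went the other way, reaching 1.7 CPM (read counts scaled to library size) in RPE1 and 0.218 in SH-SY5Y. GATA2, of that list too, stood at 2.6 to 12.3 CPM in RPE1 against 252 to 762 in SH-SY5Y. The epithelial keratin gene KRT18 stayed at or under 0.956 CPM in SH-SY5Y against 493 to 1440 in RPE1.

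The knocked-out gene was examined before any comparison. In RPE1, SDCCAG8 stood at 41.48, 35.94 and 38.61 CPM in the WT baseline libraries and at 13.41, 15.08 and 14.84 in the KO baseline libraries. After starvation it stood at 36.2, 34.75 and 36.19 in WT and at 17.59 and 17.57 in KO. The KO level was 37.4% of WT at baseline (log2 fold change -1.42, 95% interval -1.58 to -1.27, edgeR adjusted p = 3.11e-08) and 49.2% after starvation (-1.02, SE 0.0902, edgeR adjusted p = 1.53e-06). Starvation raised the remaining transcript in RPE1 KO by 0.28 on the log2 scale (edgeR adjusted p = 0.017), and the interaction of genotype and starvation was 0.40 (SE 0.117, edgeR adjusted p = 0.0353). In SH-SY5Y the WT baseline libraries held 33.44, 32.9 and 33.96 CPM of SDCCAG8 and the libraries labelled knockout 35.73, 33.32 and 31.63. The starved values were 31.97, 30.47 and 33.15 in WT and 29.5, 30.89 and 37.54 in the libraries labelled knockout. The SH-SY5Y difference was 0.01 at baseline (95% interval -0.175 to 0.187, edgeR adjusted p = 0.97) and 0.03 after starvation (95% interval -0.148 to 0.214, edgeR adjusted p = 0.811), so a lower transcript level was not detected there. A frameshift need not lower a transcript, and gene-level counts do not show the edit. Genotype in SH-SY5Y therefore rests on the labels, and the direction of every SH-SY5Y genotype difference below is drawn from libraries labelled knockout.

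**Figure D1:**
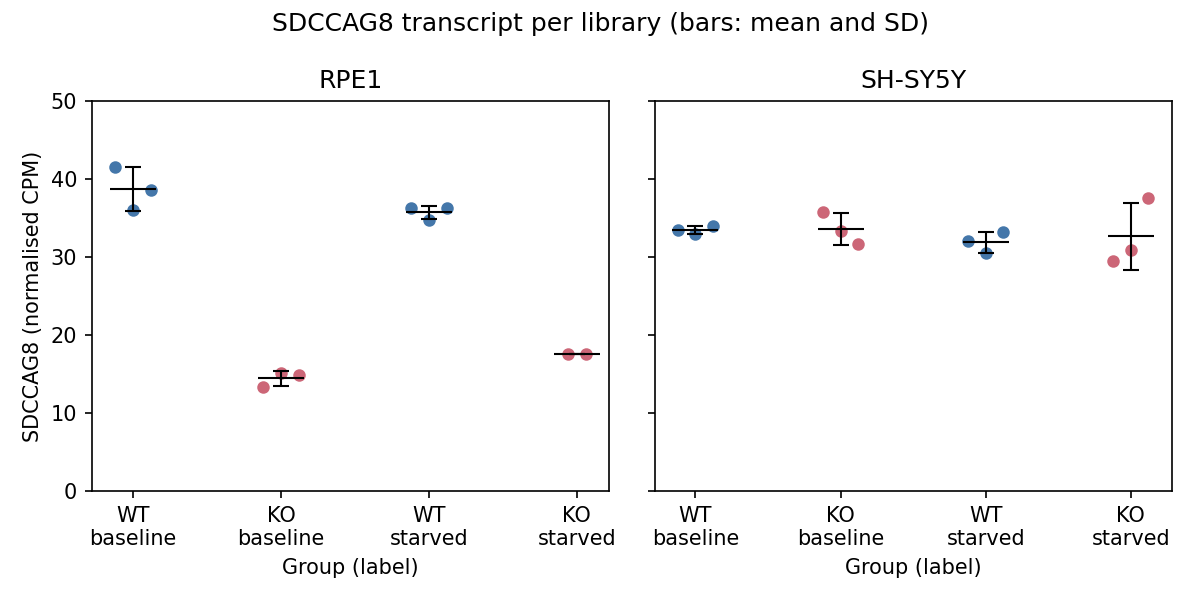
SDCCAG8 transcript in normalised CPM (vertical axis) for every library (points) of the 8 groups (horizontal axis), with bars at the group mean and error bars of 1 SD, 3 libraries per group except RPE1 KO starved with 2. The RPE1 KO means are 14.4 and 17.6 against 38.7 and 35.7 in WT, and the 4 SH-SY5Y group means lie between 31.9 and 33.6.

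The RPE1 baseline comparison asks which transcripts differ when SDCCAG8 is disrupted in dividing retinal epithelial cells. In KO, 3594 genes were higher and 3837 lower of 17663 (n = 3 and 3). The 10 most abundant genes took 5.06 to 5.23% of counts in KO and 6.74 to 6.83% in WT. Most extracellular matrix and axon guidance genes were lower, and both lists were called with a preset correlation but not with an estimated one (adjusted p = 0.0629 each). COL11A1, a fibrillar collagen chain, was at least 1220-fold lower (0 against 14.7 ± 0.59 CPM, SD). COL1A1, the main chain of type I collagen, fell by 4.16 on the log2 scale (SE 0.147, edgeR adjusted p = 7.85e-10), and the matrix protein gene TGFBI fell by 2.60 (SE 0.057, edgeR adjusted p = 1.78e-11). Of 37 measured matrix genes 3 rose, 25 fell and 9 did not pass (3 and 25 adjusted over the list alone), with a median of -1.25 on the log2 scale (camera adjusted p = 1.21e-15, and adjusted p = 0.0629 with an estimated correlation). Of 38 axon guidance genes 8 rose, 25 fell and 5 did not pass (8 and 25 adjusted over the list alone; camera adjusted p = 9.21e-05, and adjusted p = 0.0629 with an estimated correlation). This list was not chosen blind to earlier work on these cells. The guidance receptor ROBO1 went from 64.9 ± 5.1 to 5 ± 0.1 CPM, and its ligand SLIT3 fell by 2.18 (SE 0.0717).

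Cholesterol synthesis and uptake genes were higher in RPE1 KO at baseline, where 20 of 24 rose, 1 fell and 3 did not pass (20 and 1 adjusted over the list alone), with a median of 0.74 (camera adjusted p = 4.87e-06, and adjusted p = 0.0712 with an estimated correlation). DHCR7, which catalyses a last step of the pathway, rose by 1.26 (SE 0.0913, edgeR adjusted p = 3.44e-07), and lies on chromosome 11, whose genes stood at 0.273. Of 28 genes of the amino acid and endoplasmic reticulum stress responses 2 rose, 18 fell and 8 did not pass (2 and 18 adjusted over the list alone; camera adjusted p = 7.12e-07, and adjusted p = 0.0629 with an estimated correlation). Asparagine synthetase, ASNS, was at -1.75 (SE 0.0714) and the amino acid transporter gene SLC7A5 at -1.97 (SE 0.106). All but 1 of the 13 mitochondrially encoded genes fell (12, and 12 adjusted over the list alone; median -1.24, camera adjusted p = 9.66e-06, and adjusted p = 0.46 with an estimated correlation). Mitochondrial reads made up 1.44 to 1.56% of counts in the RPE1 KO baseline libraries and 2.57 to 3.32% in WT. Mesenchymal marker genes also fell, with 2 of 19 higher, 12 lower and 5 not passing (3 and 13 adjusted over the list alone; camera adjusted p = 0.0261, and adjusted p = 0.438 with an estimated correlation); LGALS1, a galectin, went from 1500 ± 84 to 765 ± 44 CPM, and lies on chromosome 22, whose genes stood at -0.603 as a whole.

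Lists tied to the function of SDCCAG8 were not called as groups in RPE1 at baseline, though single members changed. Of 39 centrosome and satellite genes 5 rose, 8 fell and 26 did not pass (5 and 8 adjusted over the list alone; camera adjusted p = 0.765). BBS4, which links satellites to the Bardet-Biedl protein complex, was at -0.61 (SE 0.0819). Among 49 cilium and intraflagellar transport genes 8 rose, 14 fell and 27 did not pass (8 and 15 adjusted over the list alone; camera adjusted p = 0.632), and the transport subunit genes IFT27 and IFT122 fell by 1.01 (SE 0.104) and 0.73 (SE 0.0926). IFT27 lies on chromosome 22, whose genes stood at -0.603 as a whole. Hedgehog genes went both ways, 5 up, 8 down and 5 not passing of 18 (5 and 8 adjusted over the list alone; camera adjusted p = 0.381). SMO, the signal transducer of the pathway, went from 34.3 ± 0.91 to 5 ± 0.2 CPM, while FOXF1, a transcription factor induced by hedgehog signals, rose by 2.94 (SE 0.166). Of 30 WNT genes 8 rose, 15 fell and 7 did not pass (8 and 16 adjusted over the list alone; camera adjusted p = 0.207). In the retinal epithelium and epithelial identity list 5 rose, 4 fell and 6 did not pass of 15 (5 and 4 adjusted over the list alone; camera adjusted p = 0.289); the phagocytosis receptor gene MERTK rose by 2.60 (SE 0.128) and keratin gene KRT8 by 1.42 (SE 0.0983). The genes beside SDCCAG8 on its chromosome held 2 lower of 3 (2 adjusted over the list alone; camera adjusted p = 0.447), among them CEP170 at -0.41. Mitosis genes numbered 7 higher and 6 lower of 30 (7 and 6 adjusted over the list alone; camera adjusted p = 0.541), and replication genes 9 higher and 3 lower of 32 (7 and 3 adjusted over the list alone; camera adjusted p = 0.445).

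Several genes switched from absent to abundant or the reverse in RPE1 KO at baseline. RCAN2, a calcineurin regulator, was at least 3530-fold higher (43.7 ± 3.9 against 0 CPM), and AQP4, a water channel, 1870-fold higher (counting interval 336 to 74000). EBF1, a transcription factor, rose by 6.16 (SE 0.168) and ELMO1, a regulator of engulfment and migration, by 5.99 (SE 0.213). SULF1, which trims heparan sulfate, was at least 1230-fold lower. PCDH7, a protocadherin, was 4780-fold lower (counting interval 858 to 189000) and TIMP3, a metalloproteinase inhibitor, 1540-fold lower (counting interval 425 to 12700). The rises of hsa-mir-7162 and ANKRD30B are uncertain, since reads of overlapping or similar genes cannot be told apart in gene counts of unstated strand.

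The starved RPE1 comparison asks the same where cells have been driven to leave the cell cycle. In KO (n = 2) against WT (n = 3), 4386 genes were higher and 3721 lower. Reads without a gene made up 4.22 to 4.25% in these KO libraries and 3.16 to 3.47% in WT, and the 10 most abundant genes took 7.18 to 7.29% of counts against 9.62 to 9.8%. Every measured mitosis gene was higher in KO, 30 of 30 (30 adjusted over the list alone), with a median of 1.02 (camera adjusted p = 2.43e-17, and adjusted p = 0.0591 with an estimated correlation). UBE2C, which helps degrade cyclins, stood at 121 ± 4.8 against 29.8 ± 1 CPM, the mitotic kinase gene AURKA rose by 1.40 (SE 0.0805), and the spindle factor gene TPX2 by 1.18 (SE 0.0693). All 32 replication genes were higher as well (32 adjusted over the list alone), with a median of 1.16 (camera adjusted p = 4.26e-20, and adjusted p = 0.0177 with an estimated correlation). The helicase subunit gene MCM4 was at 1.43 (SE 0.0656, edgeR adjusted p = 4.66e-09) and RRM2, a subunit of ribonucleotide reductase, at 1.42 (SE 0.0679). Cholesterol genes were lower, with 1 of 24 up, 19 down and 4 not passing (1 and 19 adjusted over the list alone), a median of -0.91 and camera adjusted p = 1.14e-07 (adjusted p = 0.0508 with an estimated correlation). SREBF2, the transcription factor that drives the pathway, fell by 1.27 (SE 0.079), and lies on chromosome 22, whose genes stood at -0.65 as a whole. UBE2C, AURKA and TPX2 lie on chromosome 20, whose genes stood at 0.307.

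Matrix genes were again lower in starved RPE1 KO, 3 up, 27 down and 7 not passing of 37 (3 and 27 adjusted over the list alone), with a median of -1.96 (camera adjusted p = 8.28e-27, and adjusted p = 0.0177 with an estimated correlation). COL11A1 was at least 2050-fold lower, and COL4A1, a basement membrane collagen, stood at 67.5 ± 3 against 1050 ± 120 CPM. Targets of the growth regulator YAP were lower, 4 up, 9 down and 5 not passing of 18 (4 and 11 adjusted over the list alone; camera adjusted p = 0.000502, and adjusted p = 0.0622 with an estimated correlation). CTGF was at -2.43 (SE 0.0812) and CYR61 at -1.31 (SE 0.0846). Axon guidance genes numbered 8 up, 23 down and 7 not passing of 38 (8 and 23 adjusted over the list alone; camera adjusted p = 0.00358, and adjusted p = 0.0622 with an estimated correlation), yet the receptor gene EPHB1 rose by 5.58 (SE 0.203). Interferon-response genes were higher, 17 up, 2 down and 8 not passing of 27 (18 and 2 adjusted over the list alone; camera adjusted p = 0.00358, and adjusted p = 0.314 with an estimated correlation). The antiviral genes HERC5 and OAS3 were among them, HERC5 at 2.21 (SE 0.117) and OAS3 at 2.12 (SE 0.119). Synapse genes were lower, 4 up, 12 down and 12 not passing of 28 (4 and 13 adjusted over the list alone; camera adjusted p = 0.042, and adjusted p = 0.314 with an estimated correlation). The immediate early transcription factor gene FOS stood at 190 ± 59 against 9.97 ± 2.4 CPM, within a growth-factor response list of 14 up, 7 down and 5 not passing of 26 (15 and 7 adjusted over the list alone; camera adjusted p = 0.14). SOX2, a stem cell transcription factor, was 1720-fold higher (counting interval 590 to 8360). Of the SDCCAG8 neighbours, 3 of 3 were lower (3 adjusted over the list alone; camera adjusted p = 0.154).

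The RPE1 genotype differences recurred across conditions and gathered on certain chromosomes. Of 17663 genes, 2433 were higher and 2423 lower in KO in both conditions (892 and 808 if the calls were independent), 118 rose at baseline and fell after starvation (757), 200 did the reverse (953), and the log2 fold changes had a Spearman rho of 0.625 across genes, which are not independent replicates. Genes of chromosome 22 had a median log2 fold change of -0.603 at baseline and -0.65 after starvation relative to all genes, and 73.9% and 63.2% of them were called lower. Chromosome 10 stood at -0.324 and -0.353. The genes of chromosomes 5, 7, 11, 12, 16, 20 and X lay above the median of all genes in both conditions, by 0.186 (chromosome 12, baseline) to 0.307 (chromosome 20, starved). Of 4524 calls shared by both conditions whose gene had a known chromosome, 2301 (50.9%) lay on the other chromosomes. Those held 62.9% of such tested genes. The genes of each of them lay below the median of all genes in both conditions, at -0.016 (chromosome 19, baseline) to -0.174 (chromosome 3, starved). With the median of its chromosome subtracted from each gene, the median of the matrix list was -1.23 at baseline and -1.99 after starvation, that of the cholesterol list 0.61 and -0.88, and that of the mitosis list 0.05 and 1.05.

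**Figure D2:**
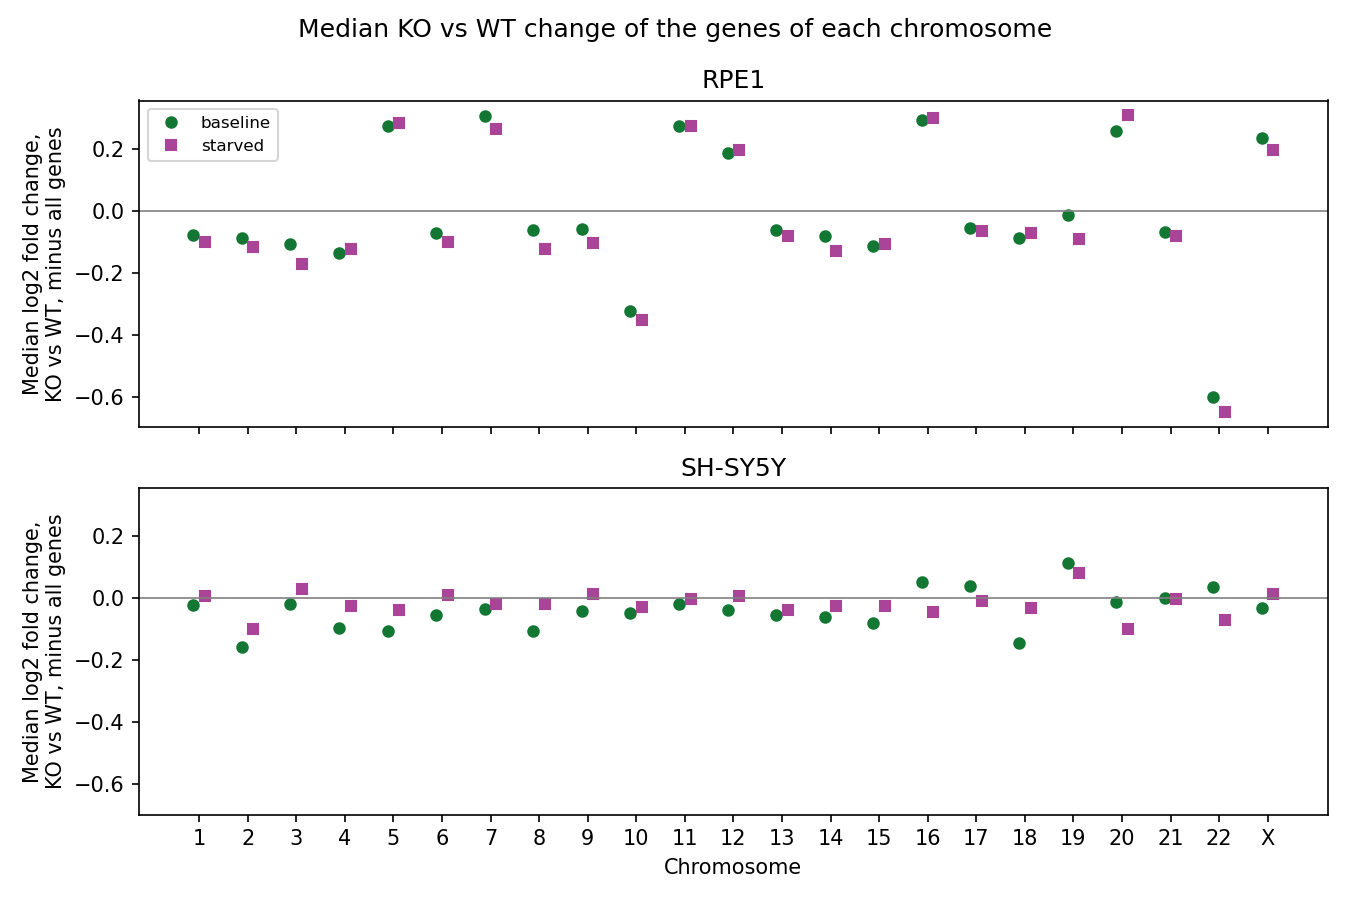
Median log2 fold change of KO against WT for the genes of each chromosome (horizontal axis) minus the median of all genes (vertical axis), at baseline and after starvation, for both lines. In RPE1, chromosome 22 lies at -0.603 and -0.65, and in SH-SY5Y the value farthest from 0 is -0.156.

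The SH-SY5Y baseline comparison asks which transcripts differ in neuron-like cells labelled knockout. There, 3215 genes were higher and 3416 lower of 19390 (n = 3 and 3). Reads without a gene made up 4.87 to 5.91% in these libraries and 3.97 to 4.69% in WT, and the 10 most abundant genes took 5.47 to 6.23% against 3.94 to 4.26%. Synapse genes fell as a group, 6 up, 25 down and 5 not passing of 36 (6 and 25 adjusted over the list alone), with a median of -0.81 (camera adjusted p = 1.37e-18, and 0.000305 with an estimated correlation). The synaptic adhesion gene LRRTM2 fell by 7.68 (SE 0.28), and SHANK1, a postsynaptic scaffold, by 5.34 (SE 0.227). Noradrenergic neuron genes fell as well, 4 up, 21 down and 7 not passing of 32 (4 and 21 adjusted over the list alone), with a median of -0.72 (camera adjusted p = 7.69e-15, and 0.00722 with an estimated correlation). The microtubule protein gene DCX fell by 2.70 (SE 0.105), the receptor kinase gene ALK by 2.66 (SE 0.106) and the growth cone gene GAP43 by 2.04 (SE 0.0827). Each of the 30 mitosis genes was lower (30 adjusted over the list alone), with a median of -0.65 (camera adjusted p = 1.3e-09, and 0.026 with an estimated correlation); the centromere histone gene CENPA stood at 20.1 ± 1.4 against 50.3 ± 2.4 CPM. Replication genes were lower in 28 of 32 (28 adjusted over the list alone; camera adjusted p = 3.33e-07, and adjusted p = 0.207 with an estimated correlation). RRM2 was at -1.57 (SE 0.0957).

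Cilium genes were higher in SH-SY5Y libraries labelled knockout at baseline, 19 up, 5 down and 25 not passing of 49 (20 and 6 adjusted over the list alone; camera adjusted p = 0.031, and adjusted p = 0.254 with an estimated correlation). WDR19, a subunit of intraflagellar transport, stood at 75.2 ± 5 against 39.2 ± 0.71 CPM. Hedgehog genes numbered 7 up, 1 down and 7 not passing of 15 (9 and 3 adjusted over the list alone; camera adjusted p = 0.0353, and adjusted p = 0.594 with an estimated correlation), with the pathway's targets GLI1 at 1.28 (SE 0.16) and PTCH1 at 0.47 (SE 0.0716). Growth-factor response genes were lower, 3 up, 14 down and 8 not passing of 25 (3 and 14 adjusted over the list alone; camera adjusted p = 0.000779, and adjusted p = 0.249 with an estimated correlation), among them the phosphatase gene DUSP4 at -1.31 (SE 0.06). Stress response genes fell, 1 up, 15 down and 12 not passing of 28 (2 and 17 adjusted over the list alone; camera adjusted p = 0.000696, and adjusted p = 0.249 with an estimated correlation). Of 24 cholesterol genes 12 fell and 12 did not pass (13 lower adjusted over the list alone; camera adjusted p = 0.0192, and adjusted p = 0.249 with an estimated correlation). Cytosolic ribosome genes were higher, 24 up, 1 down and 17 not passing of 42 (29 and 1 adjusted over the list alone; camera adjusted p = 0.000598, and adjusted p = 0.722 with an estimated correlation). Of 13 mitochondrially encoded genes 12 rose (13 adjusted over the list alone; camera adjusted p = 6.31e-08, and adjusted p = 0.253 with an estimated correlation). Mitochondrial reads took 4.10 to 5.13% of counts against 1.4 to 2.37% in WT.

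Among the largest SH-SY5Y baseline differences, IGF2BP2, an RNA-binding protein of growth control, was 87-fold higher in libraries labelled knockout (32.7 ± 3.2 against 0.381 ± 0.048 CPM), the phosphatase gene PTPRK 77.7-fold higher, and THBS2, a matrix protein, 22.9-fold higher. MAB21L2, a developmental gene, went from 29.7 ± 0.55 to 350 ± 11 CPM. CELF2, a splicing regulator, was at least 1070-fold lower, MGST1, a detoxifying enzyme, at least 1000-fold lower, and SLC6A11, a GABA transporter, at least 815-fold lower. BMP7, a secreted growth factor, fell by 8.81 (SE 0.202). The matrix list went both ways, 12 up, 9 down and 10 not passing of 31 (14 and 10 adjusted over the list alone; camera adjusted p = 0.311).

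The starved SH-SY5Y comparison repeats the question in low serum. In libraries labelled knockout 3765 genes were higher and 4221 lower (n = 3 and 3). All 30 mitosis genes were lower (30 adjusted over the list alone), with a median of -3.15 (camera adjusted p = 7.72e-97, and 7.7e-05 with an estimated correlation). The survival and spindle gene BIRC5 stood at 9.69 ± 0.53 against 119 ± 7.2 CPM, the kinesin gene KIF20A fell by 3.26 (SE 0.0833) and the kinetochore gene NDC80 by 3.45 (SE 0.0897). All 32 replication genes were lower (32 adjusted over the list alone; median -2.19, camera adjusted p = 7.17e-69, and 0.000433 with an estimated correlation). The replication initiation genes CDC45 and MCM10 were among them, CDC45 at -3.41 (SE 0.0838) and MCM10 at -3.35 (SE 0.0819). Cholesterol genes numbered 1 up, 18 down and 5 not passing of 24 (1 and 19 adjusted over the list alone; camera adjusted p = 8.02e-07, and 0.0283 with an estimated correlation). Synapse genes were lower in 23, higher in 4 and did not pass in 9 of 36 (25 and 6 adjusted over the list alone; camera adjusted p = 1.61e-11, and 0.00107 with an estimated correlation). Noradrenergic genes were lower in 20, higher in 9 and did not pass in 3 of 32 (21 and 9 adjusted over the list alone; camera adjusted p = 8.02e-07, and 0.0335 with an estimated correlation). The noradrenaline transporter gene SLC6A2 stood at 97.1 ± 6.2 against 318 ± 9.5 CPM and neurofilament gene NEFL fell by 2.78 (SE 0.101). BASP1, a growth cone protein, was 1380-fold lower (counting interval 472 to 6690).

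Mesenchymal marker genes were higher in starved SH-SY5Y libraries labelled knockout, 9 up, 3 down and 4 not passing of 16 (9 and 3 adjusted over the list alone; camera adjusted p = 0.00061, and 0.0335 with an estimated correlation). FOSL2, an AP-1 transcription factor, stood at 81.7 ± 1.7 against 11.5 ± 1.3 CPM, and WWTR1, the YAP partner TAZ, rose by 4.04 (SE 0.273). Hedgehog genes numbered 11 up and 4 not passing of 15 (11 adjusted over the list alone; camera adjusted p = 0.000587, and adjusted p = 0.299 with an estimated correlation). The transcription factor gene GLI2 was at 1.51 (SE 0.128). Cilium genes numbered 23 up, 3 down and 23 not passing of 49 (23 and 3 adjusted over the list alone; camera adjusted p = 0.0144, and adjusted p = 0.273 with an estimated correlation). Ribosome genes rose in 35 and fell in 1 of 42 (36 and 1 adjusted over the list alone; camera adjusted p = 9.75e-05, and adjusted p = 0.613 with an estimated correlation). Growth-factor response genes numbered 2 up, 16 down and 7 not passing of 25 (3 and 16 adjusted over the list alone; camera adjusted p = 0.00457, and adjusted p = 0.309 with an estimated correlation). Here 2 of 13 mitochondrially encoded genes were lower (2 adjusted over the list alone; camera adjusted p = 0.593), and mitochondrial reads took 3.78 to 4.45% of counts against 4.28 to 5.42% in WT. SH-SY5Y differences recurred across conditions, with 1728 genes higher and 2366 lower in both (624 and 744 if independent) and a Spearman rho of 0.538 across genes. The first 255 placed genes of chromosome 2, from SH3YL1 to FBXO11, lay in 5 windows at -0.845 to -0.451 relative to all genes in both conditions, and the next window at -0.0131 and 0.168. CENPA, RRM2 and ALK, given above for baseline, lie in this segment, whose genes stood at -0.625 there, as does FOSL2.

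Comparing the lines asks whether the same transcripts differ between libraries labelled knockout and WT in both cell types, though the SDCCAG8 transcript was lower only in RPE1. At baseline 419 genes were higher in both lines (532 if independent) and 801 lower in both (607), of 15834 tested in both, and rho across genes was -0.0605. Another 755 were higher in RPE1 and lower in SH-SY5Y (559 if independent), and 784 the reverse (579). After starvation 625 were higher in both (780 if independent) and 774 lower in both (705), and rho was -0.123. Here 1379 were higher in RPE1 and lower in SH-SY5Y (821) and 894 the reverse (669). Genes called in all 4 genotype comparisons numbered 170 higher and 347 lower, against 190 and 254 if the lines were independent given the calls each shared across conditions. Among them ASB9, a ubiquitin ligase adaptor, rose by 3.54 and 4.21 in RPE1 (baseline and starved) and by 2.31 and 2.66 in SH-SY5Y, and MTUS1, a microtubule-binding protein, by 2.77, 3.27, 1.91 and 1.42. HOTAIR, a long noncoding RNA antisense to the HOXC genes, rose by 3.26, 3.50, 2.25 and 1.76, though strand was not stated. CHRM3, a muscarinic acetylcholine receptor, was at least 205-fold lower in RPE1 at baseline, 434-fold lower after starvation (counting interval 77.9 to 17100), and at -2.90 and -3.35 in SH-SY5Y. TUBB4A, a neuronal tubulin, was at -2.25, -4.19, -7.06 and -7.28. The integrin gene ITGB2 rose in all 4, but without WT baseline replicate 2 its SH-SY5Y baseline call was lost (edgeR adjusted p = 0.0732).

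Starvation in RPE1 WT asks how unedited epithelial cells answer serum withdrawal. It raised 4705 genes and lowered 4578 (n = 3 and 3). Reads without a gene went from 2.99% to between 3.16 and 3.47%, and the share of the 10 most abundant genes from at most 6.83% to at least 9.62%. All 30 mitosis genes fell (30 adjusted over the list alone), with a median of -2.0 (camera adjusted p = 4.94e-64, and 0.00271 with an estimated correlation). So did all 32 replication genes (32 adjusted over the list alone; median -1.63, camera adjusted p = 1.81e-47, and 0.00213 with an estimated correlation). CDC20, an activator of the anaphase ligase, went from 183 ± 6.9 to 35 ± 0.67 CPM, cyclin gene CCNB1 fell by 2.32 (SE 0.0723), and RRM2 by 2.14 (SE 0.064). FOXO and quiescence genes rose in 19 of 20 (20 adjusted over the list alone; median 1.20, camera adjusted p = 3.31e-15, and 0.00882 with an estimated correlation), such as the transcriptional repressor gene BCL6 at 1.66 (SE 0.0713). Cholesterol genes rose, 20 up, 1 down and 3 not passing of 24 (20 and 1 adjusted over the list alone; camera adjusted p = 1.72e-07, and 0.0335 with an estimated correlation); HMGCS1, an early enzyme of the pathway, went from 38.4 ± 1.7 to 175 ± 28 CPM. Stress response genes numbered 5 up, 18 down and 5 not passing of 28 (5 and 19 adjusted over the list alone; camera adjusted p = 5.25e-10, and 0.031 with an estimated correlation), with the serine synthesis gene PSAT1 falling from 143 ± 2.1 to 12.1 ± 0.43 CPM. Among genes at 5 CPM or more in a group that met the rest of the naming rule, CHI3L1, a secreted glycoprotein, rose most, at 7.90 (SE 0.138). SERPINB2, a protease inhibitor, fell most among them, at -5.83 (SE 0.153).

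Further lists were tested in starved RPE1 WT. Matrix genes rose, 30 up, 2 down and 5 not passing of 37 (31 and 2 adjusted over the list alone; camera adjusted p = 5.58e-11, and adjusted p = 0.0503 with an estimated correlation). The proteoglycan gene BGN was at 2.90 (SE 0.123). Retinal epithelium and epithelial identity genes rose in 11 of 15 (11 adjusted over the list alone; camera adjusted p = 0.000257, and adjusted p = 0.0733 with an estimated correlation). The eye transcription factor genes OTX2 and PAX6 were among them, OTX2 at 1.33 (SE 0.0821) and PAX6 at 0.96 (SE 0.0641). Centrosome genes numbered 3 up, 19 down and 17 not passing of 39 (3 and 20 adjusted over the list alone; camera adjusted p = 0.00224, and adjusted p = 0.357 with an estimated correlation). PLK4, the kinase that starts centriole duplication, was at -1.81 (SE 0.106). Axon guidance genes numbered 23 up, 5 down and 10 not passing of 38 (23 and 5 adjusted over the list alone; camera adjusted p = 0.019, and adjusted p = 0.0733 with an estimated correlation). Interferon-response genes numbered 15 up, 4 down and 8 not passing of 27 (15 and 4 adjusted over the list alone; camera adjusted p = 0.0245, and adjusted p = 0.309 with an estimated correlation). In the noradrenergic list, of which 12 genes were measured in RPE1, 6 rose, 2 fell and 4 did not pass (6 and 2 adjusted over the list alone; camera adjusted p = 0.00669, and adjusted p = 0.0528 with an estimated correlation). Its median was 1.03, or 1.60 without the 1 gene that had 3 or fewer reads in each group. Its mean level in RPE1 WT was low, at 0.00016 log2 CPM at baseline and 0.999 after starvation. Cilium genes numbered 21 up, 6 down and 22 not passing of 49 (21 and 6 adjusted over the list alone) and were not called (camera adjusted p = 0.0577). WDR19 was at 0.98 (SE 0.0653).

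Starvation in RPE1 KO (n = 2 against 3) raised 4858 genes and lowered 4248, of which 3215 and 3134 moved the same way in WT (1294 and 1101 if independent). Reads without a gene went from 2.95 to 3.55% up to 4.22 to 4.25%. All 30 mitosis genes and all 32 replication genes fell (30 and 32 adjusted over the list alone), with medians of -1.01 and -0.58 (camera adjusted p = 1.29e-16 and 8.37e-08, and adjusted p = 0.0655 for each with an estimated correlation). Cholesterol genes fell, 1 up, 15 down and 8 not passing of 24 (1 and 15 adjusted over the list alone; camera adjusted p = 7.23e-06, and adjusted p = 0.0655 with an estimated correlation). Quiescence genes rose in 18 of 20 (18 adjusted over the list alone; camera adjusted p = 3.92e-11, and 0.0354 with an estimated correlation), led by TXNIP, a thioredoxin inhibitor, at 3.58 (SE 0.0983). Targets of YAP fell, 4 up, 9 down and 5 not passing of 18 (4 and 9 adjusted over the list alone; camera adjusted p = 0.000237, and adjusted p = 0.0655 with an estimated correlation). Cilium genes rose in 25, fell in 4 and did not pass in 20 of 49 (25 and 4 adjusted over the list alone; camera adjusted p = 0.0308, and adjusted p = 0.391 with an estimated correlation). IFT140 was at 1.14 (SE 0.0887). Hedgehog genes numbered 12 up, 2 down and 4 not passing of 18 (12 and 2 adjusted over the list alone; camera adjusted p = 0.0488, and adjusted p = 0.194 with an estimated correlation). This hedgehog call was lost with the replicate number as a block. HHIP, an inhibitor of the pathway, fell by 3.61 (SE 0.157). After starvation the mean cilium list level was 4.52 log2 CPM in both RPE1 genotypes. The hedgehog list stood at 3.6 in KO and 3.61 in WT, and the centrosome list at 4.99 and 4.65. The median change of KO against WT there was -0.0415 for cilium, -0.0931 for hedgehog and 0.243 for centrosome genes. A cilium call in KO starvation and none in WT is thus no sign of a higher level in starved KO.

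Notch genes rose in 9 of 17 in starved RPE1 KO (9 up and 1 down adjusted over the list alone; camera adjusted p = 0.00889, and adjusted p = 0.0655 with an estimated correlation). Interferon-response genes numbered 17 up, 1 down and 9 not passing of 27 (18 and 1 adjusted over the list alone; camera adjusted p = 0.00022, and adjusted p = 0.116 with an estimated correlation). Stress response genes numbered 7 up, 16 down and 5 not passing of 28 (7 and 16 adjusted over the list alone; camera adjusted p = 0.000441, and adjusted p = 0.0825 with an estimated correlation). Glial and Schwann cell marker genes rose in 7 of 9 (7 adjusted over the list alone). Their median was 1.19, or 1.47 without the 1 gene that had 3 or fewer reads in each group. The list was called (camera adjusted p = 0.0134, and adjusted p = 0.0764 with an estimated correlation). The glutamate transporter gene SLC1A3 was at 4.42 (SE 0.296). The mean level of the glial list was low in RPE1 KO, at -0.411 log2 CPM at baseline and 1.11 after starvation. Axon guidance, noradrenergic and retinal identity genes were also called higher (18 up and 4 down of 38, 5 and 3 of 12, and 7 and 1 of 15, with 18 and 4, 6 and 4, and 8 and 1 adjusted over the list alone; camera adjusted p = 0.0134, 0.022 and 0.0479, and adjusted p = 0.0764, 0.0825 and 0.231 with an estimated correlation). The retinal identity call was lost with the replicate number as a block. The noradrenergic list had a mean level of only -0.237 log2 CPM at baseline and 0.883 after starvation in RPE1 KO. In SH-SY5Y libraries labelled knockout it stood at 5.93 and 6.33. Of 13 mitochondrially encoded genes 12 rose, and 12 adjusted over the list alone (camera adjusted p = 1.03e-06, and adjusted p = 0.194 with an estimated correlation). Mitochondrial reads were at 4.29 to 4.35% after starvation. The immediate early gene FOS went from 0.568 ± 0.13 to 190 ± 59 CPM and EGR1 from 1.85 ± 0.12 to 168 ± 65.

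The RPE1 interaction asks where starvation acted differently in KO and WT, and 1772 genes were more positive and 1166 more negative in KO. Mitosis genes fell less on starvation in KO, with an interaction of 0.99 (30 of 30 called, 30 adjusted over the list alone; camera adjusted p = 2.25e-34, and 0.0135 with an estimated correlation). So did replication genes, at 1.03 (30 of 32 called, 31 adjusted over the list alone; camera adjusted p = 6.23e-39, and 0.000965 with an estimated correlation). Mean mitosis list level went from 7.10 to 5.10 log2 CPM in WT and from 7.13 to 6.15 in KO. Cholesterol genes moved oppositely, rising in WT and falling in KO (20 of 24 negative, 22 adjusted over the list alone; median -1.52, camera adjusted p = 1.73e-49, and 0.000418 with an estimated correlation). Targets of YAP numbered 1 positive, 7 negative and 10 not passing of 18 (4 and 8 adjusted over the list alone; camera adjusted p = 8.31e-06, and 0.0302 with an estimated correlation), CTGF at -2.26 (SE 0.102). Matrix genes numbered 3 positive, 17 negative and 17 not passing of 37 (3 and 20 adjusted over the list alone; camera adjusted p = 5.54e-10, and adjusted p = 0.0927 with an estimated correlation). Centrosome genes numbered 9 positive and 30 not passing of 39 (14 adjusted over the list alone; camera adjusted p = 0.000477, and adjusted p = 0.384 with an estimated correlation), CEP250, a centriole linker, at 1.25 (SE 0.131). Stress response genes (12 positive and 4 negative of 28, and 14 and 6 adjusted over the list alone) and mitochondrially encoded genes (12 of 13 positive, 12 adjusted over the list alone) were called too (camera adjusted p = 0.000436 and 2.77e-11, and adjusted p = 0.151 for each with an estimated correlation). SOX2 had an interaction of 5.08 (SE 1.21, edgeR adjusted p = 0.012), which rests on WT baseline replicate 3, without which it was 2.84 (edgeR adjusted p = 0.455).

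**Figure D3:**
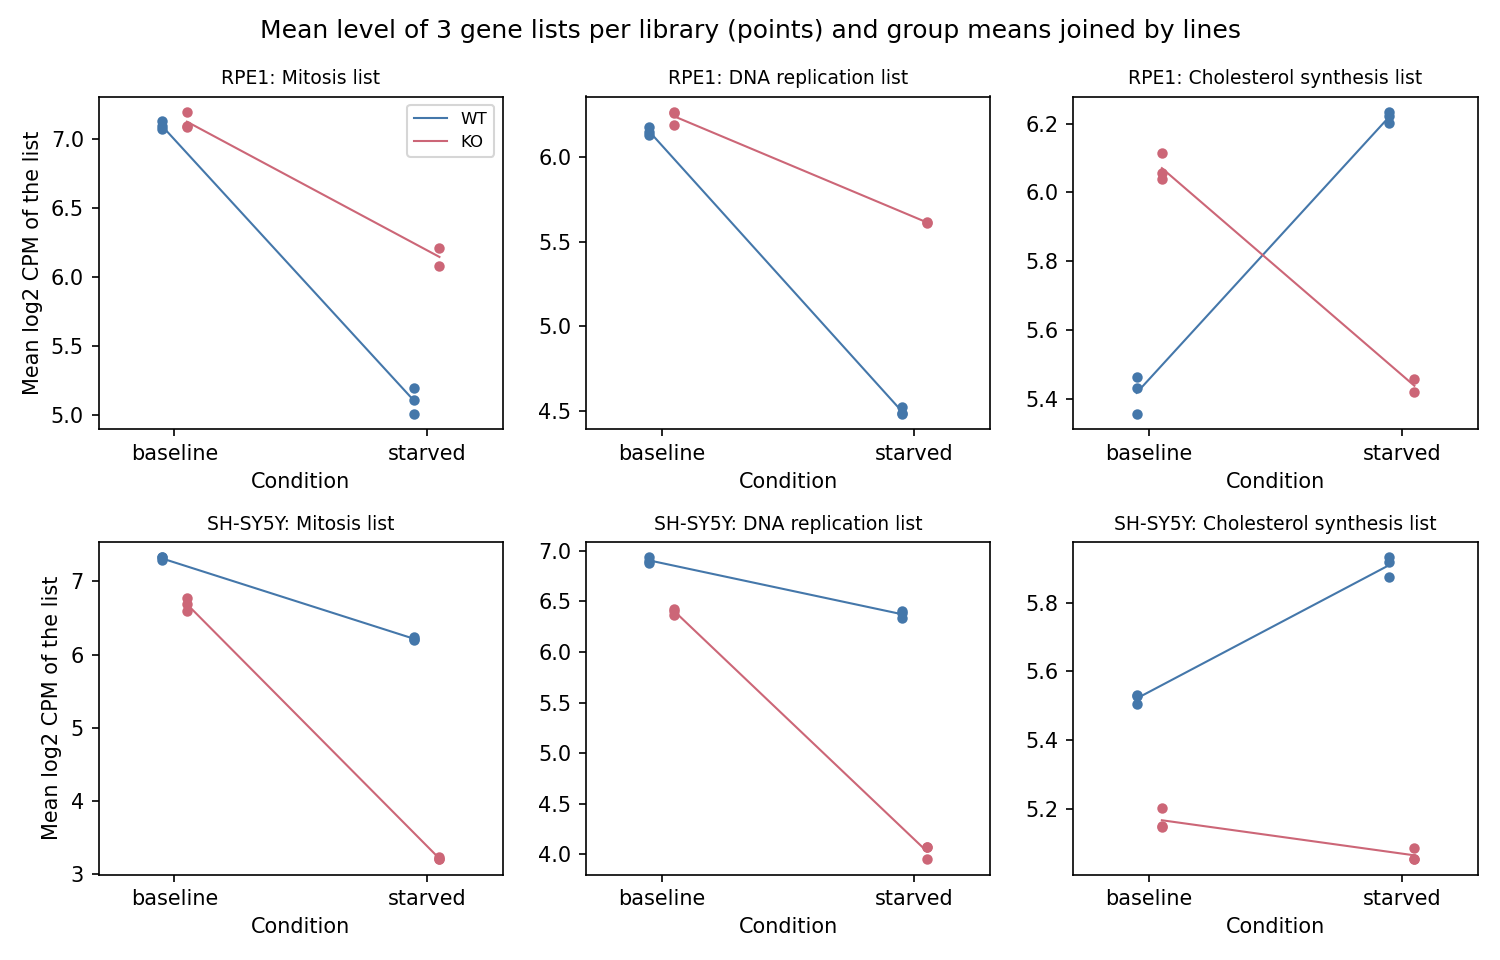
Mean log2 CPM (vertical axis) of the mitosis, replication and cholesterol lists at baseline and after starvation (horizontal axis) in both lines, with points for libraries and lines joining the means of WT and of libraries labelled knockout. The mitosis mean after starvation is 5.10 in RPE1 WT and 6.15 in RPE1 KO, and 6.22 in SH-SY5Y WT and 3.21 in SH-SY5Y libraries labelled knockout.

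Starvation in SH-SY5Y WT raised 4098 genes and lowered 4233 (n = 3 and 3), the response of unedited neuron-like cells. Reads without a gene went from 3.97 to 4.69% up to 5.85 to 6.2%, and the share of the 10 most abundant genes from 3.94 to 4.26% up to 5.78 to 6.7%. Synapse genes rose, 27 up, 2 down and 7 not passing of 36 (28 and 2 adjusted over the list alone; median 0.76, camera adjusted p = 4.85e-10, and 0.00079 with an estimated correlation), such as the presynaptic scaffold gene PCLO at 1.57 (SE 0.0969). The chromogranin gene CHGA, a marker of secretory granules, went from 220 ± 36 to 2440 ± 94 CPM. The noradrenergic list held 15 up, 10 down and 7 not passing of 32 (15 and 10 adjusted over the list alone; camera adjusted p = 0.0312, and adjusted p = 0.301 with an estimated correlation). Mesenchymal marker genes fell in 15 of 16 (15 adjusted over the list alone). Their median was -1.35, or -1.67 without the 1 gene that had 3 or fewer reads in each group. The list was called (camera adjusted p = 7.98e-20, and 0.000695 with an estimated correlation). The transcription factor gene SNAI2 was at -4.07 (SE 0.126) and intermediate filament gene VIM at -1.99 (SE 0.0743). Matrix genes fell, 3 up, 22 down and 6 not passing of 31 (3 and 22 adjusted over the list alone; camera adjusted p = 7.98e-20, and 0.0434 with an estimated correlation). All 30 mitosis genes fell (30 adjusted over the list alone; median -1.11, camera adjusted p = 1.96e-25, and 0.001 with an estimated correlation). Of 32 replication genes 26 fell (27 adjusted over the list alone; camera adjusted p = 2.85e-07, and adjusted p = 0.0909 with an estimated correlation). Genes of the p53 response numbered 3 up, 12 down and 12 not passing of 27 (3 and 12 adjusted over the list alone; camera adjusted p = 0.00399, and 0.0409 with an estimated correlation). TP53I3 was at -2.96 (SE 0.116).

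Interferon-response genes also fell in starved SH-SY5Y WT, 2 up, 16 down and 7 not passing of 25 (2 and 17 adjusted over the list alone; camera adjusted p = 0.000366, and 0.0409 with an estimated correlation). WNT genes fell, 2 up, 18 down and 13 not passing of 33 (2 and 18 adjusted over the list alone; camera adjusted p = 0.000153, and adjusted p = 0.0804 with an estimated correlation), the receptor gene FZD4 at -2.36 (SE 0.106). Cholesterol genes rose, 12 up, 1 down and 11 not passing of 24 (13 and 2 adjusted over the list alone; camera adjusted p = 0.00797, and adjusted p = 0.149 with an estimated correlation). Growth-factor response genes (6 up and 10 down of 25, 6 and 10 adjusted over the list alone) and YAP targets (1 up and 7 down of 13, 2 and 8 adjusted over the list alone) were called lower (camera adjusted p = 0.0332 and 0.0129, and adjusted p = 0.415 and 0.0701 with an estimated correlation). The growth-factor call was lost with the replicate number as a block. Ribosome genes rose in 39 of 42, and 40 adjusted over the list alone (camera adjusted p = 6.97e-10, and adjusted p = 0.348 with an estimated correlation). All 13 mitochondrially encoded genes rose (13 adjusted over the list alone; camera adjusted p = 2.31e-07, and adjusted p = 0.246 with an estimated correlation). Mitochondrial reads were at 1.4 to 2.37% before and 4.28 to 5.42% after. The adrenergic receptor gene ADRA2A fell by 7.61 (SE 0.243) and IGFBP3, which binds insulin-like growth factors, from 169 ± 8.6 to 3.35 ± 0.18 CPM.

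In SH-SY5Y libraries labelled knockout, starvation raised 4172 genes and lowered 4758 (n = 3 and 3), of which 2361 and 2909 moved the same way in WT (882 and 1039 if independent). Mitosis genes fell in 30 of 30 (30 adjusted over the list alone), with a median of -3.70 (camera adjusted p = 3.13e-127, and 2.3e-05 with an estimated correlation). Replication genes fell in 32 of 32 (32 adjusted over the list alone; median -2.37, camera adjusted p = 5.75e-72, and 0.000299 with an estimated correlation). KIF20A went from 142 ± 11 to 7.25 ± 0.35 CPM. Synapse genes rose, 23 up, 3 down and 10 not passing of 36 (24 and 5 adjusted over the list alone). Their median was 0.64, or 0.66 without the 1 gene that had 3 or fewer reads in each group. The list was called (camera adjusted p = 9.79e-06, and 0.00615 with an estimated correlation). Mesenchymal genes fell in 12, rose in 2 and did not pass in 2 of 16 (13 and 2 adjusted over the list alone; camera adjusted p = 6.79e-05, and 0.0306 with an estimated correlation). Matrix genes numbered 3 up, 23 down and 5 not passing of 31 (4 and 23 adjusted over the list alone; camera adjusted p = 2.53e-11, and adjusted p = 0.288 with an estimated correlation). WNT genes (7 up and 12 down of 33, 7 and 13 adjusted over the list alone) and noradrenergic genes (19 up and 9 down of 32, 21 and 9 adjusted over the list alone) were called (camera adjusted p = 0.0413 and 0.0188, and adjusted p = 0.335 and 0.33 with an estimated correlation). Ribosome genes rose in 41 of 42 (41 adjusted over the list alone; camera adjusted p = 1.24e-10, and adjusted p = 0.335 with an estimated correlation). TNR, a matrix protein of neural tissue, rose by 8.63 (SE 0.195) and CUX2, a neuronal transcription factor, fell by 8.67 (SE 0.172).

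The SH-SY5Y interaction was positive for 1410 genes and negative for 2242. Mitosis genes fell further on starvation in libraries labelled knockout, with a median interaction of -2.45 (30 of 30 called, 30 adjusted over the list alone; camera adjusted p = 6.32e-136, and 9.95e-06 with an estimated correlation). Replication genes did likewise, at -1.80 (31 of 32 called, 31 adjusted over the list alone; camera adjusted p = 6.52e-89, and 0.000134 with an estimated correlation). BIRC5 had an interaction of -2.92 (SE 0.109, edgeR adjusted p = 1.17e-09). Mesenchymal genes fell less (9 of 16 positive, 9 and 1 negative adjusted over the list alone; median 0.53, camera adjusted p = 7.05e-06, and 0.0135 with an estimated correlation). Cholesterol genes numbered 1 positive, 15 negative and 8 not passing of 24 (1 and 16 adjusted over the list alone; camera adjusted p = 4.61e-05, and adjusted p = 0.0665 with an estimated correlation). Interferon-response genes (10 positive and 2 negative of 25, 11 and 2 adjusted over the list alone), hedgehog genes (3 of 15, 4 adjusted over the list alone) and axon guidance genes (12 positive and 9 negative of 40, 14 and 11 adjusted over the list alone) were called higher (camera adjusted p = 0.0224, 0.0224 and 0.0492, and adjusted p = 0.151, 0.636 and 0.639 with an estimated correlation). Mitochondrially encoded genes were negative in 12 of 13 (12 adjusted over the list alone; camera adjusted p = 3.18e-10, and adjusted p = 0.249 with an estimated correlation).

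Across 240 pairings of 24 lists and 10 comparisons, camera made 99 calls with its preset correlation, and 34 held with an estimated correlation. In RPE1 these were replication and matrix in the starved genotype comparison, mitosis, replication, cholesterol, quiescence and stress response in WT starvation, quiescence in KO starvation, and mitosis, replication, cholesterol and YAP targets in the interaction. In SH-SY5Y they were mitosis, synapse and noradrenergic genes in the baseline comparison, with replication, cholesterol and mesenchymal genes added in the starved one. The others were mitosis, p53, matrix, synapse, mesenchymal and interferon genes in SH-SY5Y WT starvation, mitosis, replication, synapse and mesenchymal genes in starvation of libraries labelled knockout, and mitosis, replication and mesenchymal genes in the interaction. Median, mean and test differed in sign in 33 of the 240 pairings, of which 0 were called. Each pairing of the p53 list other than starved SH-SY5Y WT, and of the SDCCAG8 neighbours in all comparisons, was not called.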

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

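The thinning and abundant-gene tests, the RPE1 permutation test, the SH-SY5Y permutation test within replicate numbers, the count of splits by pairs parted, the tests of a difference between lines and the chromosome windows were chosen only after the results were seen.

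Knockout differences in RPE1 recurred in both conditions and gathered on certain chromosomes. A difference in copy number between the cells labelled knockout and wild type may account for part of them, since the genes of chromosome 22 deviated by -0.603 in the smaller of both conditions, and all 6 of its windows of 50 or more genes lay below -0.15. Of windows on the 7 raised chromosomes 71 of 91 lay above 0.15, against 25 of 183 beyond either bound on the remaining chromosomes. The raised chromosomes were picked by the same bound on the same genes, so this contrast is built in and adds no support. The windows show only how far a shift spread, with 7 of 16 above 0.15 on chromosome 12 and 5 of 9 on X. On chromosome 10, 9 of 12 windows lay below -0.15, and windows ranged from -0.782 to -0.0988. The remaining chromosomes were no unshifted reference. The genes of each lay below the median of all genes in both conditions, at -0.016 (chromosome 19, baseline) to -0.174 (chromosome 3, starved). Of them only chromosome 19 had a window above 0.15 in both conditions, and it had 1. They held 50.9% of the shared calls and 62.9% of the tested genes with a known chromosome. Whether losing SDCCAG8 changed those calls stays open. In SH-SY5Y the smaller deviation of all of chromosome 2 was -0.0987, where copy number and an effect of the label cannot be told apart. Of 308 windows 21 lay beyond 0.15. Among them were the first 5 of chromosome 2 (255 genes) at -0.845 to -0.451, so a segment may differ in copy number. Another 6 lay above 0.15 on chromosome 19, where every window from DLL3 to RPL23AP79 stood at 0.114 to 0.294.

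In RPE1 the interaction covered 2938 genes, and its mitosis list had a median of 0.988. A real difference in how far knockout cells leave the cell cycle is consistent with this, and so is a difference in growth or density between cultures, which the counts cannot test. Thinning every library to 38.6 M counts gave 0.989. Thinning keeps the expected share of each gene, so it could hardly move this median and does not decide on unequal library totals. Without the 100 most abundant and the mitochondrial genes the median was 1, so it did not depend on the counts of those genes. Chance is unlikely, since 1 of 100 residual permutations, the real order, called as many genes (3069 with limma), though the highest other called 1999.

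In SH-SY5Y the interaction covered 3652 genes and had the opposite sign, with a mitosis median of -2.45. Here too thinning to 48.3 M counts left -2.45, which does not decide on library totals for the same reason. Leaving out abundant genes gave -2.47, so this median did not depend on their counts either. Chance is unlikely, since 1 of 100 residual permutations, the real order, called as many genes (3699 with limma, against 393 at most otherwise). That test ignored the pairing by replicate number seen in 3 SH-SY5Y comparisons, but with a replicate block and permutation within numbers again only 1 of 100, the real order, called as many (4965, against 4197 at most otherwise). Cells labelled knockout that leave the cycle further in low serum, or a difference between clones, could each give this pattern, and the SDCCAG8 transcript was not lower in them.

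Other RPE1 interactions were 1.03 for the replication list, -1.52 for cholesterol genes and -0.273 for YAP targets. Single genes were KCNK15 at 7.66, SOX2 at 5.08, FOSB at 4.85, CHAC1 at 4.48, NPR3 at -3.96, BMP6 at -3.302, DHRS3 at -3.295, VSTM2L at -3.06 and SDCCAG8 at 0.398. The SOX2 call was lost without WT baseline replicate 3 (2.84, adjusted p = 0.455). Of 225 genes named in other RPE1 comparisons 118 had an interaction call, against 16.6% of all tested genes. The named genes were picked for called changes in the same libraries, so the higher share is no separate evidence.

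Other SH-SY5Y interactions were -1.8 for the replication list and 0.529 for mesenchymal genes. Single genes were FLT1 at 6.62, TNR at 6.04, NTNG1 at 5.36, NYAP2 at 4.37, CUX2 at -7.8, ADAMTS2 at -6.37, ISLR2 at -6.02 and BRINP1 at -5.58. Of 220 genes named in other SH-SY5Y comparisons 128 had an interaction call, against 18.8% of all tested genes. These too were picked for called changes in the same libraries.

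Unlike the main fits, the test of a difference between lines used 1 fit of all 23 libraries over 21430 genes. The genotype effect differed between lines for 6922 genes at baseline, 7826 after starvation and 3497 in the interaction. Only 15834 genes were tested in both of the separate fits. For a gene scarcely counted in 1 line, the difference is mainly the effect in the other line. The median difference, RPE1 minus SH-SY5Y, was 1.03 for cholesterol genes at baseline, 4.1 for mitosis and 3.37 for replication genes after starvation, and 3.46, 2.93 and -0.979 for mitosis, replication and cholesterol genes in the interaction.

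For 6 comparisons the libraries allowed 10 splits into 3 and 3, too few for a share under 0.05. Only 1 split, the real one, called as many genes as were called in RPE1 at baseline (7431), SH-SY5Y at baseline (6631) and starved (7986), and on starvation of RPE1 WT (9283) and SH-SY5Y WT (8331), with 0 at most in other splits. For starvation of SH-SY5Y libraries labelled knockout the real split called 8930 genes and the highest other 699. In the 3 SH-SY5Y comparisons whose numbers pair the libraries, 4 splits part all 3 pairs, and those other than the real one called 0 genes, so the 699 came from 1 of the 6 that part fewer. No group held 4 or more libraries, so single-library outliers were not tested.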

How the results depend on the processing

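All alternatives here were planned. Requiring a 1.5-fold change lowered every count, as its construction implies. Genotype calls became 2268 and 3217 in RPE1 and 1810 and 2906 in SH-SY5Y (baseline, starved), starvation calls 3564 and 3687 in RPE1 and 2785 and 3361 in SH-SY5Y (WT, KO), and interaction calls 833 and 1188. Calls shared by lines became 164 and 292, and calls shared by conditions 1528 and 1143. Of 99 list calls 34 held with an estimated correlation and 96 with a replicate block, which added 3 others, and fry made 181 calls in all. The SDCCAG8 difference in SH-SY5Y changed sign near 0, at -0.0025 with RLE, -0.00238 with DESeq2, and -0.00659, -0.04 and -0.0778 without single libraries, where the highest values were 0.0469 at baseline and 0.1 starved. Lists with a reversed sign and no call had adjusted p of 0.819 (hedgehog, RPE1 interaction, block), 0.919 (retinal identity, SH-SY5Y baseline, block), 0.7 (p53, SH-SY5Y starved, fry), 0.275 (synapse, SH-SY5Y interaction, fry) and, on starvation of SH-SY5Y labelled knockout, 1 (hedgehog, fry), 0.501 (axon guidance, fry), 0.345 and 0.931 (stress response, fry and block). The cause was not tested.

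Leaving out each library gave 6077 to 8037 and 7018 to 8159 RPE1 genotype calls, 5180 to 7345 and 6839 to 8717 in SH-SY5Y, 2324 to 3342 RPE1 interaction calls and 2836 to 4437 in SH-SY5Y. Starvation calls ranged from 8169 to 9673 and 7753 to 9627 in RPE1 and from 6833 to 9155 and 7732 to 9313 in SH-SY5Y. Shared calls ranged from 966 to 1338 and 1200 to 1525 between lines, and from 4146 to 5035 and 3319 to 4248 between conditions. SDCCAG8 in RPE1 ranged from -1.48 to -1.37 at baseline and -1.04 to -1.01 after starvation. With each library left out, 870 to 879 of 880 named results kept their call, where results of the line not refitted count as kept. Over the refits alone, 10026 of 10122 kept their call. Over all comparisons 19 of 33 same-number correlations were over 0.1 (-0.665 to 0.888) and 20 of 33 tries correlated best with their own number. With 3 pairs, all passed in 3 SH-SY5Y comparisons, in which the block changed no call of a list or named gene. The replicate block gave 7305 and 7854 RPE1 genotype calls, 8194 and 9157 in SH-SY5Y, and 2746 and 4943 interaction calls. It ended the hedgehog (adjusted p = 0.0943) and retinal identity (0.0516) calls on RPE1 KO starvation and the growth-factor call on SH-SY5Y WT starvation (0.0571). It added growth-factor calls on RPE1 KO starvation (0.0246) and in the RPE1 interaction (0.0124), and SDCCAG8 neighbours on SH-SY5Y WT starvation (0.0424), with no other list call changed. For the interactions, a fit of only the compared groups is the main model and was not run.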

Other observations

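The gene groups here were chosen only after the data were seen, as were the medians with chromosome medians subtracted. The camera p-values of these 4 groups were adjusted over the 4 alone, so they cannot be set beside those of the planned lists. Because the groups were picked from the same data, these p-values describe the groups and do not test them. HOX genes, which set position along the body axis, were higher in RPE1 KO at baseline, where 21 of 23 rose and 0 fell, with a median of 2.88 (camera adjusted p = 1.47e-24, and 0.000688 with an estimated correlation). After starvation 20 rose and 0 fell, with a median of 2.96 (camera adjusted p = 3.5e-21, and 0.00108 with an estimated correlation). HOXC8 rose by 2.99, HOXA3 by 3.43, HOXB3 by 2.52 and HOXD3 by 4.24 at baseline, 1 gene from each cluster, and the clusters lie on 4 chromosomes. In SH-SY5Y libraries labelled knockout 3 of 16 rose and 2 fell at baseline, and after starvation 3 rose and 7 fell, and neither was called (camera adjusted p = 0.432 and 0.863).

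Clustered protocadherins, adhesion proteins that give neurons their surface identity, rose on starvation in RPE1, 16 of 21 in WT (median 1.74, camera adjusted p = 6.48e-13, and 0.00034 with an estimated correlation) and 17 of 21 in KO (median 2, camera adjusted p = 2.31e-19, and 8.94e-05 with an estimated correlation). The RPE1 interaction was positive for 6 of 21 (camera adjusted p = 0.0107, and adjusted p = 0.0533 with an estimated correlation). In SH-SY5Y the list was not called on starvation (camera adjusted p = 0.899 in WT and 0.753 in libraries labelled knockout). Members of the gamma cluster share exons, so their counts are uncertain one by one. MHC class I genes, which present antigen, fell on starvation in SH-SY5Y WT, 9 of 11 (median -0.807, camera adjusted p = 7.02e-05, and adjusted p = 0.131 with an estimated correlation), and had a positive interaction there for 6 of 11 (camera adjusted p = 2.95e-05, and adjusted p = 0.0918 with an estimated correlation). In RPE1 they went the other way on starvation, 9 higher and 1 lower of 13 in WT (median 0.68, camera adjusted p = 0.0204, and adjusted p = 0.676 with an estimated correlation) and 9 higher and 0 lower in KO (median 0.702, camera adjusted p = 0.00389, and adjusted p = 0.347 with an estimated correlation). Replication-dependent histone genes rose in 18 and fell in 6 of 44 in starved SH-SY5Y libraries labelled knockout (camera adjusted p = 0.0032, and adjusted p = 0.688 with an estimated correlation), although mitosis and replication genes fell there, and had a positive interaction for 10 and a negative one for 2 (camera adjusted p = 0.000792, and adjusted p = 0.318 with an estimated correlation).

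With the median of its chromosome subtracted from each gene, RPE1 list medians at baseline and after starvation were 0.0724 and 1.07 for replication, -0.599 and -0.493 for axon guidance, -0.559 and -0.0327 for stress response, and 0.576 and 0.69 for interferon genes.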
